A study of Mus musculus with 3 samples.

How the data were processed

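Total RNA-seq of the chromatin fraction was available for 3 libraries of Lipid A-treated, bone-marrow-derived macrophages of the mouse, all in 1 group. The authors deposited gene tables with expected counts and TPM, in the column layout of RSEM, made from an alignment to the transcriptome of mm10 with GENCODE M21. The aligner and its version are not given in the sources used here. The authors also deposited a transcript table of expected counts and TPM in the same layout, and another transcript table with estimated counts and TPM in the column layout of kallisto, made directly from the sequence reads. Per the file headers, expected counts are estimated fragments that need not be whole, and deposited TPM values are scaled to the same total in each table. The program names are not stated with the files, so only the layout is named. The gene tables gave the main values and the table made from the reads, summed to genes, served as the alternative.

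The gene tables held 55536 annotated genes, 22028 of them protein-coding. Entries that name no gene were left out of library sizes, namely 26248 numeric entries with 24, 29 and 25 counts, 96 ERCC spike-in entries with 0 counts and the phiX control with 157826, 55880 and 46173 counts (1.13%, 0.324% and 0.279% of all counts). The depth per library was 13802716, 17187524 and 16502809 expected counts in annotated genes, of which 9214611, 10393180 and 10281977 lay in protein-coding genes. The table made from the reads held 21183097, 31002629 and 28194259 estimated counts. A count of 0 allows up to 3 counts, or 0.217, 0.175 and 0.182 CPM, the count scaled by the library total. Such limits and the Wilson 95% intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

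Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule named the 15 protein-coding and 8 other genes with the highest mean TPM, the 3 highest members of each list with up to 3 undetected ones in list order, and the 10 protein-coding genes with the largest SD of log2 CPM among those with a mean of at least 5 TPM and 100 counts. It also named 12 genes in every case and the 5 genes with the highest retained-intron share, where 22 genes tied at 100% and the order of the table decided. A gene counted as detected with a mean of at least 10 counts. The 14 functional lists were immediate-early, NF-kB feedback and target, cytokine, chemokine, interferon-stimulated, negative regulator, antimicrobial, Toll-like receptor 4 pathway, macrophage identity, cell-cycle, glycolysis, oxidative phosphorylation, cholesterol and lipid, and ribosomal protein genes. The 10 marker lists covered neutrophils, T cells, B cells, natural killer cells, dendritic cells, fibroblasts, erythroid cells, mast cells and basophils, endothelial cells and megakaryocytes. Mitochondrially encoded genes, histone genes, nuclear long non-coding RNAs and small structural RNAs were described by level only. Cxcl11, Mx2, Rn45s, Iglc1 and Ahsp were asked for but not found under these symbols among the genes eligible for their lists.

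List levels were medians of percentile ranks of mean log2(TPM + 1) among all protein-coding genes, tested against 100000 random lists. Differences between lists were tested with 100000 reassignments of members. Counts were rounded to whole numbers for edgeR, DESeq2 and the chi-square test. Dispersion was estimated with edgeR from a design with an intercept only and TMM factors, for genes with a mean of at least 10 counts, and variation beyond counting noise was tested per gene with a chi-square test against Poisson sampling. Spread and library differences of lists used log2 CPM with a prior count of 0.5 and were compared with 10000 random lists matched on mean expression in 20 bins, for lists with at least 5 genes. All permutation tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each family at 0.05. The tests run across genes, which are not independent replicates. Some lists share members, among them the negative regulators with other response lists, so their results are not separate. No contrast between groups was fitted, as there is 1 group. The spread measures only differences between these 3 samples, which the labels number as biological replicates while giving all of them the same strain-level donor. The retained-intron share was the percent of a gene's TPM in transcripts annotated as retained intron, for genes with a mean of at least 1 TPM and with both kinds of transcript.

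The alternatives were a pseudocount of 0.1, other minimum levels, CPM in place of TPM, DESeq2 size factors, total count scaling, the quantification made from the reads and leaving out each replicate in turn. Chosen after the data were seen were TPM rescaled over protein-coding genes for list differences, total count scaling for library differences, and the alternatives for single named genes. On simulated data with Poisson counts, the noise test called 10 of 14130 unchanged genes, and 64.2%, 82.1% and 98.5% of genes changed 1.5-, 2- and 4-fold in a library. The level test called 4% of random lists and 99% of lists with 10 of 20 members from the top decile, and the difference test 5% of random pairs and 100% of pairs that differed 4-fold. For the spread test the shares were 3% of random lists, 0% at a 1.5-fold and 100% at a 2-fold change, and for library differences 5%, 80% and 100%. Simulated genes varied independently of each other, so these rates need not hold for lists whose members move together. edgeR estimated simulated coefficients of variation of 10%, 20% and 30% as 9.97%, 20.1% and 29.8%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.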

Results

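The series held 3 libraries of 1 group, numbered by the labels as biological replicates 1, 2 and 3. They were made from bone-marrow-derived macrophages of C57BL/6J mice, which are phagocytes grown from marrow in culture. Lipid A, the part of bacterial lipopolysaccharide that activates Toll-like receptor 4, was given at 100 ng/ml for 12 h. After a washout of 12 h, Lipid A was given again at 100 ng/ml for 40 min. RNA bound to chromatin, a fraction rich in transcripts still being made, was depleted of ribosomal RNA and sequenced. RNA input was 1 µg for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3. The depth was 13802716, 17187524 and 16502809 expected counts in annotated genes, in the order of the replicates. At least 10 counts were found for 13855, 14810 and 14164 genes. The treatment schedule addresses what macrophages transcribe shortly after a repeated exposure to Lipid A. Cells without the earlier exposure and cells without the later one were not analysed here, so levels are described and no induction is given. Values are mean TPM ± SD over the 3 libraries (n = 3) unless another unit is named, and positions are on mm10 with the GENCODE M21 annotation.

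The 15 most abundant protein-coding transcripts on chromatin included immune genes and splicing factor genes, which describes these 15 and is no test of either group. Lilrb4a (ENSMUSG00000112148.1, chromosome 10, 51490956 to 51496611), an inhibitory receptor of myeloid cells, had the highest level, 2372 ± 736 TPM. Its neighbouring paralog Lilr4b (ENSMUSG00000112023.1, chromosome 10, 51480632 to 51486703) had 1698 ± 520. H2-K1 (ENSMUSG00000061232.16, chromosome 17, 33996017 to 34000347), which presents antigen on MHC class I, had 1894 ± 204, and the interferon-stimulated gene Mx1 (ENSMUSG00000000386.15, chromosome 16, 97447035 to 97462907) had 1827 ± 380. Acod1 (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573), which makes itaconate, had 1179 ± 328. The others of the 15 highest were Zeb2 with 1371 ± 216, Fyb with 1237 ± 154, Ikbke with 1193 ± 25.8, Tnfaip2 with 1168 ± 378, Fth1 with 1112 ± 49.6, Rbm39 with 1104 ± 111, Rsrp1 with 1084 ± 161, Tcirg1 with 1068 ± 231, Sirpa with 1063 ± 125 and Hnrnpa2b1 with 1018 ± 84.1. In the quantification made directly from the sequence reads, Ikbke had 1940, Rbm39 1965 and Sirpa 1816 TPM. Across 10952 protein-coding genes with a mean of at least 10 counts, Spearman's rho of log2(TPM + 1) was 0.974 between replicates 1 and 2, 0.980 between 1 and 3 and 0.970 between 2 and 3. Pearson's r was 0.977, 0.984 and 0.973. These 3 correlations are across genes, which are not independent replicates.

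Among the genes named in advance, the inflammatory cytokine genes spanned a wide range. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) had 506 ± 139 TPM and Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139) had 330 ± 86.9. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) had 4.06 ± 2.13, and Il12b had 1.71 ± 1.11, with 2.51, 0.44 and 2.19 in replicates 1, 2 and 3. Il10 (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974), an anti-inflammatory cytokine, had 21.2 ± 8.79. The NF-kB inhibitors Nfkbia and Tnfaip3 had 359 ± 103 and 546 ± 190, and Irak3, an inhibitor of Toll-like receptor signalling, had 30.8 ± 6.11. The chemokine genes Cxcl10 and Ccl5 had 308 ± 60.5 and 572 ± 106. Tlr4 itself had 9.46 ± 3.61, and Csf1r, the receptor for the macrophage growth factor, had 180 ± 17.5. In the quantification made from the reads, Il1b had 558, Nfkbia 575, Tlr4 16.8 and Il12b 3.13 TPM.

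**Figure D1:**
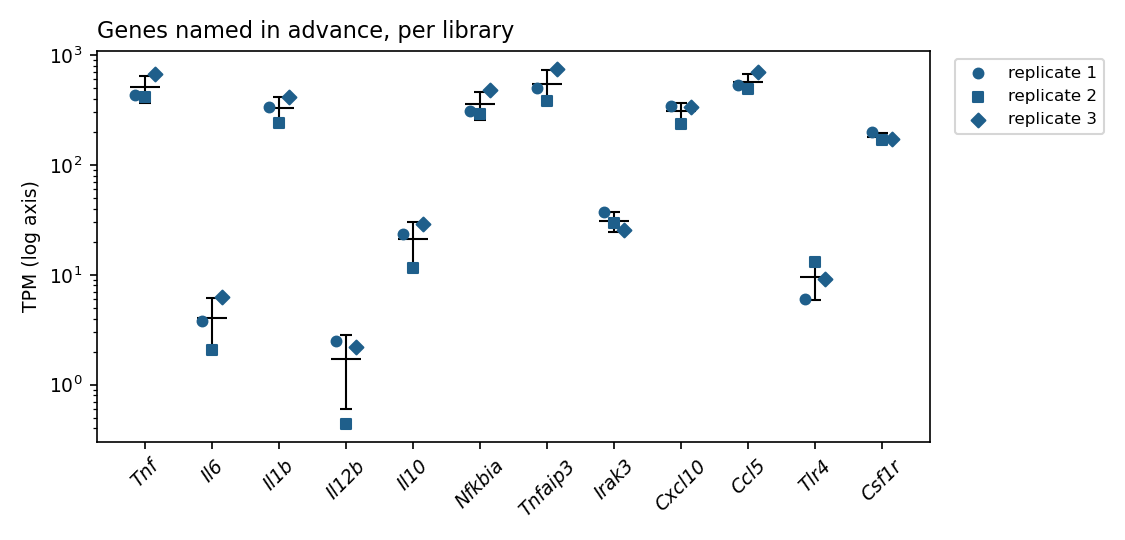
TPM on a log axis of the 12 genes named before the data were examined, 1 point per library, with the mean as a horizontal line and the SD as bars (n = 3). Tnf, Il1b, Nfkbia, Tnfaip3, Cxcl10 and Ccl5 had means between 308 and 572, while Il6 had 4.06 and Il12b 1.71.

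Long non-coding genes held most of the counts outside protein-coding genes, and a pair of loci, Gm42418 inside an rRNA gene and Gm26917 next to it, held a large part of these. Protein-coding genes held 63.2% ± 3.23 of expected counts and long non-coding genes 32.4% ± 3.42 (SD, n = 3). Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), a nuclear RNA of splicing speckles, held 10.1% ± 1.35. Gm26917 and Gm42418, annotated as long non-coding genes beside each other on chromosome 17, together held 17.5% ± 3.45, with 14.7%, 21.4% and 16.5% in replicates 1, 2 and 3. Gm42418 lies wholly inside the rRNA gene CT010467.1, on the opposite strand. None of the words of 25 bases in Gm26917 occur in an annotated rRNA gene. The longest annotated nuclear rRNA transcript has 1849 bases, too short to hold the large-subunit rRNA. Ribosomal RNA sequence outside annotated rRNA genes would not be matched either, so this comparison cannot tell whether Gm26917 counts come from ribosomal RNA. The other long non-coding genes held 4.81% ± 0.468. Of the classes used here as signs of cytoplasmic RNA, mitochondrially encoded genes held 0.0394% ± 0.00930 and ribosomal protein genes 0.0954% ± 0.00679. No other RNA fraction was analysed here, so these shares are given without a comparison. Replication-dependent histone genes held 0.00559% ± 0.00201. Nuclear rRNA genes held 0.525% ± 0.276, with 0.251%, 0.803% and 0.521% per library, and 1.56% in the quantification made from the reads. The widest Wilson 95% interval of a per-library share in this account spanned 0.0387 percentage points, which covers counting error only.

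Small structural RNAs held 1.099% ± 0.332 of counts but 53.6% of TPM. TPM divides by length, so short transcripts weigh more, but annotated lengths do not account for the size of this gap. Gm26447 (chromosome 16, 23111301 to 23111429) had 51482 TPM from a mean of 966 counts. Malat1 (chromosome 19, 5795690 to 5802672) had 29821 TPM from a mean of 1610880 counts. The cause was not tested. Protein-coding genes held 30.1% of TPM and long non-coding genes 12.9%. The small structural share of TPM was 60.6%, 49.5% and 50.6% in replicates 1, 2 and 3. This left less TPM for other genes in replicate 1, and the SDs of TPM include this shift. The highest TPM values outside protein-coding genes belonged to the small nucleolar RNA gene Gm22988 with 78262 ± 23482, the RNase MRP RNA Rmrp with 64376 ± 13284, Gm26917 with 58612 ± 15418, the small nucleolar RNA gene Gm26447 with 51482 ± 5406, Snord15b with 31827 ± 6563, Malat1 with 29821 ± 5871, Gm25776 with 15059 ± 3673 and Gm22513 with 14648 ± 9016. The quantification made from the reads gave far lower TPM for the small ones, with 8450 for Gm22988, 26193 for Rmrp, 2740 for Gm26447, 3735 for Snord15b, 1798 for Gm25776 and 3117 for Gm22513. Without replicate 1, Gm22513 had 9506 TPM. Of 7 abundant small structural RNA genes listed in advance, 5 were detected, led after Rmrp by Rn7sk with 14461 ± 4871 and Rn7s1 with 7860 ± 2767, while Terc and Vaultrc5 had a mean under 10 counts. Rn7sk had 7368 and Rn7s1 3591 TPM in the quantification made from the reads. Of 21 nuclear long non-coding RNAs, 18 were detected, led after Malat1 by Neat1 with 2125 ± 225 and Xist, the RNA that silences an X chromosome, with 1147 ± 136. Tsix, Meg3 and Miat were not detected. Of 37 mitochondrially encoded genes 10 were detected, with mt-Co1 at 193 ± 17.6, mt-Atp8 at 158 ± 38.2 and mt-Nd6 at 60.0 ± 13.4 TPM, and mt-Atp8 at 50.7 in the quantification made from the reads. The undetected ones included mt-Tf, mt-Tv and mt-Tl1. Of 67 histone genes 24 were detected, with Hist3h2a at 9.77 ± 1.33, Hist2h2aa2 at 8.79 ± 4.85 and Hist1h4k at 6.13 ± 0.809 TPM. Hist2h2aa2 had 3.06 TPM in the quantification made from the reads, and Hist1h1t, Hist1h1a and Hist1h2ba were among those not detected.

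The level of each gene list among protein-coding genes describes which programmes were abundant in chromatin-bound RNA at this time. Level alone does not separate new transcription from RNA made earlier. Genes of the NF-kB pathway stood highest. All 21 NF-kB feedback and target genes were detected and all 21 lay in the top decile of protein-coding genes, with a median of 234 TPM and a median percentile of 99.1. Ikbke and Tnfaip2 led this list, followed by Sod2, a mitochondrial superoxide dismutase gene, with 809 ± 181. All 29 interferon-stimulated genes were detected, with a median of 152 TPM and a median percentile of 98.4, and 28 lay in the top decile. After Mx1 the highest were Irf1 with 756 ± 128 and Rsad2 with 715 ± 121. The immediate-early genes, which are transcribed within minutes of a stimulus, were all detected (21 of 21) at a median percentile of 91.1, led by Klf6 with 272 ± 77.1, Zfp36 with 213 ± 50.7 and Dusp2 with 184 ± 65.5.

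Of 19 chemokine genes 12 were detected in the gene tables, against 17 in the quantification made from the reads. Their median percentile was 91.7, with Cxcl2 at 447 ± 161 TPM between Ccl5 and Cxcl10, and 7 were not detected in the gene tables, among them Ccl17, Ccl22 and Ccl24. Of 21 cytokine genes 17 were detected and 6 lay in the top decile, with a median percentile of 78.1. Tnfsf9, a ligand that stimulates T cells, followed Tnf and Il1b with 171 ± 117 TPM, and had 105 without replicate 3. Il12a, Csf2 and Csf3 were among the 4 cytokine genes not detected. Of 22 negative regulators of Toll-like receptor signalling 20 were detected, at a median percentile of 87.7, with Trim30a at 247 ± 29.7 TPM after Tnfaip3 and Nfkbia, and without Sigirr and Il1r2. Of 20 antimicrobial, scavenger and pattern-recognition genes 15 were detected, at a median percentile of 89.3. Acod1 led them, followed by the pattern receptor gene Clec4e with 594 ± 204 and the scavenger receptor gene Stab1 with 523 ± 203, while Camp, Slpi and Hp were among the 5 not detected. All 22 components of the Toll-like receptor 4 pathway were detected, at a median percentile of 91.4, with Tbk1 at 205 ± 14.7, Irak2 at 182 ± 37.0 and Cd14 at 121 ± 35.3. The quantification made from the reads gave 318 for Tbk1 and 383 for Irak2.

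Macrophage identity genes were all detected (25 of 25), at a median percentile of 94.3, led by Adgre1, which encodes the F4/80 antigen, with 368 ± 35.6 TPM, and by the cathepsin genes Ctsb with 341 ± 61.4 and Ctsd with 229 ± 58.9. Of 20 cholesterol and lipid handling genes 19 were detected, at a median percentile of 93.2, with Abca1 at 134 ± 16.1, Fabp5 at 131 ± 23.5 and Soat1 at 78.6 ± 6.73. The undetected one was Ch25h. Ribosomal protein genes lay at a median percentile of 83.9, with 76 of 80 detected. Rpl10 had 119.5 ± 27.3, Rps9 91.0 ± 20.9 and Rpl3 55.7 ± 19.6, and Rpl3l, Rps27l and Rpl39l were not detected. All 15 glycolysis genes were detected, at a median percentile of 83.3, with Pkm at 76.1 ± 15.4, Pfkfb3 at 54.3 ± 11.0 and Pfkp at 37.8 ± 7.52. All 20 nuclear-encoded oxidative phosphorylation genes were detected, at a median percentile of 80.3, with Atp5b at 67.2 ± 12.1, Sdha at 42.8 ± 5.01 and Ndufs1 at 23.9 ± 5.11. Cell-cycle genes were near the middle, at a median percentile of 58.1, with 19 of 23 detected. Mki67, a proliferation marker, had 63.3 ± 27.1, Pcna 20.3 ± 2.87 and Top2a 5.22 ± 2.76, and Ccnb1, Ccnb2 and Cdc20 were not detected. In the quantification made from the reads, Sdha had 69.9, Ndufs1 54.9 and Top2a 8.09 TPM.

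In the two-sided permutation test across protein-coding genes, 13 of the 14 functional lists stood above random genes, and the direction was the same in each of the 3 libraries. For 9 lists, all those described so far except the antimicrobial, cytokine, glycolysis, oxidative phosphorylation and cell-cycle lists, the permutation p was 2e-05, the smallest these draws can give, and 5.33e-05 after adjustment over 24 lists. The raw and adjusted permutation p were 6e-05 and 0.000144 for the antimicrobial list, 0.0014 and 0.00305 for oxidative phosphorylation, 0.00254 and 0.00508 for glycolysis, 0.0042 and 0.00775 for cytokine genes, and 0.43 and 0.543 for cell-cycle genes. The test is across genes, which are not independent replicates. Its background held all 22028 protein-coding genes, of which 10952 had a mean of at least 10 counts. A list of genes expressed in these cells therefore passes easily, whatever its function. With the background limited to genes with a mean of at least 10 counts, glycolysis genes lay at percentile 66.4 and oxidative phosphorylation genes at 60.4, no longer past the threshold, and cell-cycle genes at 18.9, below the background. With CPM in place of TPM, oxidative phosphorylation genes lay at 71.2, also not past the threshold.

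Most marker lists of other cell types had few members detected in the gene tables. None of 10 natural killer cell markers was detected, and Ncr1 and Klrb1c had 0 counts, which allows up to 3 counts or 0.217, 0.175 and 0.182 CPM in replicates 1, 2 and 3. Neutrophil markers had 1 of 12 detected, Csf3r with 103 ± 16.3 TPM, while Ngp had 0.07, 0.95 and 0.15 in replicates 1, 2 and 3 and S100a8, S100a9 and Ly6g were not detected. Of 12 T cell markers 4 were detected, among them Cd28 with 12.8 ± 3.56, Il7r with 11.9 ± 5.81 and Cd4 with 6.16 ± 0.823. B cell markers had 1 of 11 detected, Cd22 with 3.65 ± 1.05. Dendritic cell markers had 4 of 10, led by Batf3 with 5.18 ± 2.68, erythroid markers 1 of 9, Alas2 with 7.36 ± 2.91, and mast cell and basophil markers 2 of 10, led by Hdc with 1.15 ± 0.358. Endothelial markers had 3 of 10 and megakaryocyte markers 6 of 10 detected, and Vwf, which is in both lists, had 34.6 ± 13.8. Kdr had 4.03 ± 2.45 TPM, or 2.62 without replicate 1. Fibroblast markers had 3 of 12 detected, all collagen genes, and Col3a1 had 0, 0.26 and 0.82 TPM, Col1a1 0, 0.37 and 0.42 and Col1a2 0, 0.29 and 0.44 in replicates 1, 2 and 3. More markers had a mean of at least 10 counts in the quantification made from the reads, with 4 of 12 for neutrophils, 8 of 12 for T cells, 3 of 11 for B cells, 3 of 10 for natural killer cells, 7 of 10 for dendritic cells and 6 of 12 for fibroblasts. It had 2 of 9 for erythroid cells, 3 of 10 for mast cells and basophils, 4 of 10 for endothelial cells and 7 of 10 for megakaryocytes. There, Alas2 had 18.0, Hdc 2.36, Pecam1 9.45 against 2.14, and Klre1 4.29 TPM against 0, 0.1 and 0.07 per library in the gene tables. Col1a1 had 1.41 TPM there against a mean of 0.263, Col1a2 0.652 against 0.243 and Col3a1 0.280 against 0.36.

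The median percentile was 35.7 for neutrophil, 39.7 for T cell, 38.1 for B cell, 15.8 for natural killer cell, 41.9 for dendritic cell, 41.0 for fibroblast, 15.8 for erythroid, 15.8 for mast cell and basophil, 39.9 for endothelial and 50.02 for megakaryocyte markers. The percentile of neutrophil markers was 16.6 without replicate 1, and 18.9, 18.1 and 18.5 in replicates 1, 2 and 3 alone. From the reads, erythroid markers lay at 27.0. None of these 10 lists passed the permutation test, with adjusted p from 0.193 to 0.995. Of the 22028 protein-coding genes 6966 had no count in any library, so the lowest percentile a gene can take is 15.8. With the background limited to genes with a mean of at least 10 counts, the detected dendritic cell markers lay at percentile 5.14 and the fibroblast markers at 0.881, both past the threshold on the low side, and megakaryocyte markers at 21.4, not past it. In the quantification made from the reads, natural killer cell markers lay at 16.2 and mast cell and basophil markers at 9.23, also past it.

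**Figure D2:**
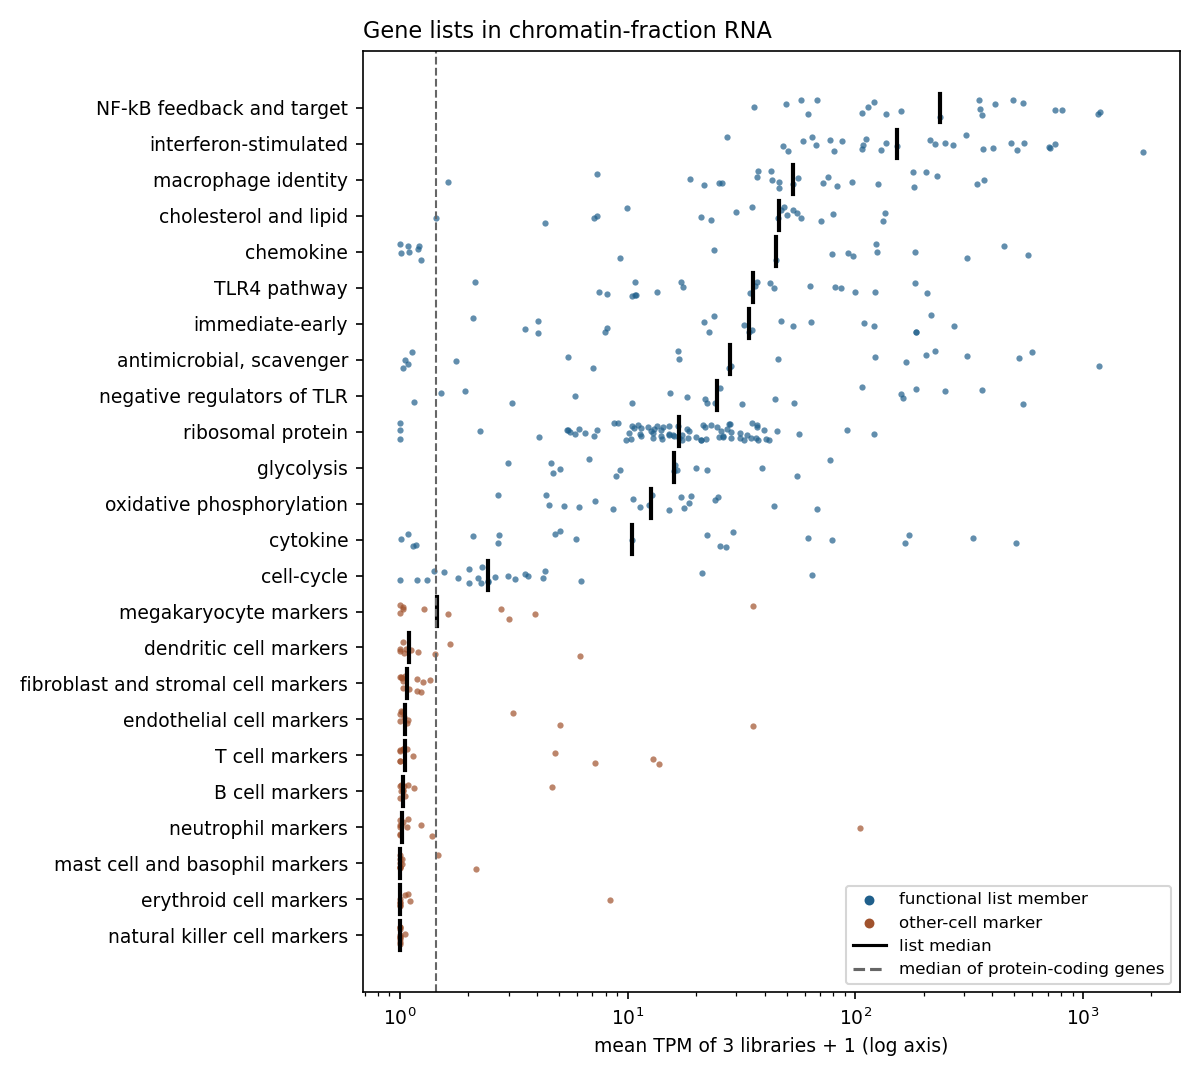
Mean TPM of the 3 libraries plus 1 on a log axis for each member of the functional lists (blue) and of the marker lists of other cell types (brown), with list medians as black bars and the median of protein-coding genes as a dashed line. NF-kB genes (median 234 TPM) and interferon-stimulated genes (152) lie far to the right of cytokine genes (9.50) and of the marker lists, whose medians are at or under 0.453.

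The comparison of lists with each other asked whether RNA of cytokine genes was as abundant as that of the other response genes. NF-kB feedback and target genes had a median 21.6 times that of cytokine genes on the TPM + 1 scale, a log2 difference of 4.43 with 4.43 ± 0.39 over the libraries (SD, n = 3). The fold was 9.78 among genes with a mean of at least 10 counts and 13.3 in the quantification made from the reads. Interferon-stimulated genes were 14.6 times as high as cytokine genes, a log2 difference of 3.87, with 3.91 ± 0.20 over the libraries. This fold was 6.61 among genes with a mean of at least 10 counts, 8.58 from the reads and 24.2 with CPM in place of TPM. Macrophage identity genes exceeded ribosomal protein genes by a log2 difference of 1.67, or 3.19-fold, with 1.67 ± 0.38 over the libraries, and by 8.96-fold with CPM. Each of these differences had the same sign in 3 of 3 libraries. The two-sided permutation p across genes was 3e-05 for the NF-kB comparison (adjusted 8e-05, over 8 comparisons), and 1e-05 for each of the others (adjusted 4e-05), the smallest these draws can give.

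Immediate-early genes, chemokine genes, negative regulators and antimicrobial genes also had higher medians than cytokine genes, by log2 differences of 1.71, 1.82, 2.23 and 1.41, but these did not pass the test (adjusted permutation p of 0.222, 0.455, 0.222 and 0.455). Over the libraries the differences were 1.72 ± 0.39, 1.82 ± 1.01, 2.10 ± 0.27 and 1.42 ± 0.29 (SD, n = 3). Among genes with a mean of at least 10 counts they were 0.57, 2.19, 0.54 and 2.37, with CPM 2.22, 1.77, 3.15 and 1.66, and from the reads 0.35, 0.46, 2.52 and 0.36. Glycolysis genes and oxidative phosphorylation genes differed by 0.35, with an adjusted permutation p of 0.699. The cytokine list spans Tnf and Il1b as well as undetected genes such as Csf2, so its median describes no single member.

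Genes of the inflammatory response varied more between libraries than genes matched on expression, as did cell-cycle genes. The median SD of log2 CPM over the 3 libraries was 0.62 for 17 cytokine genes, against 0.23 for genes matched on expression, 0.60 against 0.19 for 12 chemokine genes, 0.57 against 0.20 for 15 antimicrobial genes and 0.47 against 0.20 for 21 NF-kB genes. It was 0.42 against 0.20 for 21 immediate-early genes, 0.36 against 0.20 for 29 interferon-stimulated genes, 0.35 against 0.20 for 20 negative regulators and 0.51 against 0.34 for 19 cell-cycle genes. The 76 ribosomal protein genes were less variable than matched genes, with 0.20 against 0.25. The two-sided permutation test with matched lists gave p = 0.0002, the smallest possible, and 0.0005 after adjustment over 15 lists for 6 of these lists, with 0.0028 and 0.006 for negative regulators, 0.0136 and 0.0255 for cell-cycle genes and 0.0154 and 0.0257 for ribosomal protein genes. Not past the threshold were glycolysis genes (0.33 against 0.22, adjusted permutation p = 0.0672), Toll-like receptor 4 pathway components (0.22 against 0.19, 0.362), macrophage identity genes (0.22 against 0.19, 0.362), cholesterol and lipid genes (0.24 against 0.18, 0.191), oxidative phosphorylation genes (0.24 against 0.25, 0.893) and megakaryocyte markers (0.35 against 0.35, 0.995).

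Leaving out replicate 2 lowered most of these values. The median SD was then 0.34 for cytokine, 0.26 for chemokine, 0.28 for antimicrobial, 0.18 for NF-kB and 0.26 for immediate-early genes and 0.20 for negative regulators, all still past the threshold. Interferon-stimulated genes had 0.10, cell-cycle genes 0.20 and ribosomal protein genes 0.15 without replicate 2, none past the threshold, and cell-cycle genes then lay below their matched genes. Without replicate 3, immediate-early genes had 0.32, negative regulators 0.26 and ribosomal protein genes 0.18, not past the threshold. Glycolysis genes passed it with 0.40 without replicate 1 and 0.35 without replicate 2, and fell to 0.13 without replicate 3, while macrophage identity genes passed it with 0.20 without replicate 2. In the quantification made from the reads, cell-cycle genes had 0.36 and did not pass, and glycolysis genes had 0.38 and passed. Over all 14330 genes with a mean of at least 10 rounded counts, the common biological coefficient of variation was 22.3%, and 7867 genes varied beyond counting noise (54.9%, chi-square test, Benjamini-Hochberg). The test takes reads as independent counts and compares with Poisson sampling alone. It therefore does not separate biological variation from RNA input or other library differences. Without replicate 2 the coefficient was 16.9% and 3912 of 14021 genes varied beyond counting noise.

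The most variable single genes included Nos2 (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase gene, with 32.0, 3.79 and 11.0 TPM in replicates 1, 2 and 3. Its mean was 15.6 TPM, or 7.38 without replicate 1, and 29.6 in the quantification made from the reads. The chemokine gene Cxcl1 had 32.3, 16.4 and 83.0 TPM, and 24.4 on average without replicate 3. The cystine transporter gene Slc7a11 had 12.5, 3.75 and 13.6, the collagenase gene Mmp13 9.41, 2.67 and 8.85, and the GTPase gene Gem 8.45, 3.94 and 17.6. Sh3bgrl2 had 63.8, 32.8 and 96.7 and Prkg1 6.79, 2.57 and 11.0, and like the genes named before them both were lowest in replicate 2. All were chosen for their large spread, so this says nothing about genes in general. Slc13a3 had 30.9, 36.1 and 7.48. Zc3h11a had 0.01, 11.1 and 17.9 TPM and Gm49369 had 47.7, 4.04 and 32.3, but both overlap other genes. The 4 overlapping genes of the Zc3h11a locus summed to 521, 447 and 595 CPM, and Gm49369 with Ctsd to 287, 317 and 294.

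The comparison of each library with the mean of the others showed which lists moved together. In replicate 2, cytokine genes had a median log2 CPM difference of -1.01 and were lower in 16 of 17 members, chemokine genes had -0.96, NF-kB genes -0.77, immediate-early genes -0.62, antimicrobial genes -0.61, interferon-stimulated genes -0.54 and negative regulators -0.41. Genes matched on expression had -0.03, -0.13, -0.25, -0.08, -0.15, -0.23 and -0.10. All 29 interferon-stimulated genes were lower in replicate 2, as were 20 of 21 NF-kB genes and 20 of 21 immediate-early genes. Higher in replicate 2 were 7 of 20 negative regulators and 4 of 15 antimicrobial genes. The negative regulators share Dusp1, Il10, Il1rn, Tnip1, Tnfaip3, Nfkbia and Trim30a with other response lists, so their difference is not separate from those of these lists. Cell-cycle genes were higher in replicate 2, by 0.61 against 0.18 for matched genes, in 17 of 19 members, although their most abundant member Mki67 had 72.3, 32.9 and 84.8 TPM. Ribosomal protein genes had -0.06 against 0.12, which total count scaling moved together to 0.09 against 0.27, and with a mean of at least 100 counts they had 0.02 against 0.13 and did not pass the test.

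In replicate 3, immediate-early genes were higher by 0.52, NF-kB genes by 0.58, cytokine genes by 0.58, chemokine genes by 0.51 and negative regulators by 0.21, while macrophage identity genes had -0.14 and glycolysis genes -0.42. Their matched genes had 0.03, 0.09, 0.01, 0.04, 0.04, 0.04 and -0.02, in this order. In replicate 1, cytokine genes were higher by 0.47, chemokine genes by 0.35, interferon-stimulated genes by 0.40, antimicrobial genes by 0.40 and glycolysis genes by 0.30, and cell-cycle genes had -0.39. Genes matched to these lists had 0.03, 0.09, 0.16, 0.11, -0.02 and -0.09. The replicate 1 difference of antimicrobial genes was 0.20 with a mean of at least 100 counts, and that of cell-cycle genes -0.16 in the quantification made from the reads, neither past the threshold. That quantification gave -0.31 for macrophage identity genes in replicate 3. Among the 45 combinations of library and list, 22 passed the two-sided permutation test with matched lists, with adjusted p from 0.000818 to 0.0413. With 3 libraries the comparisons are not independent, since a low library makes the others high. Members of a list can also move together, which random matched lists do not reflect. Total count scaling moved the median gene by -0.01, 0.10 and -0.09 in replicates 1, 2 and 3 relative to TMM, and list and matched genes moved alike.

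**Figure D3:**
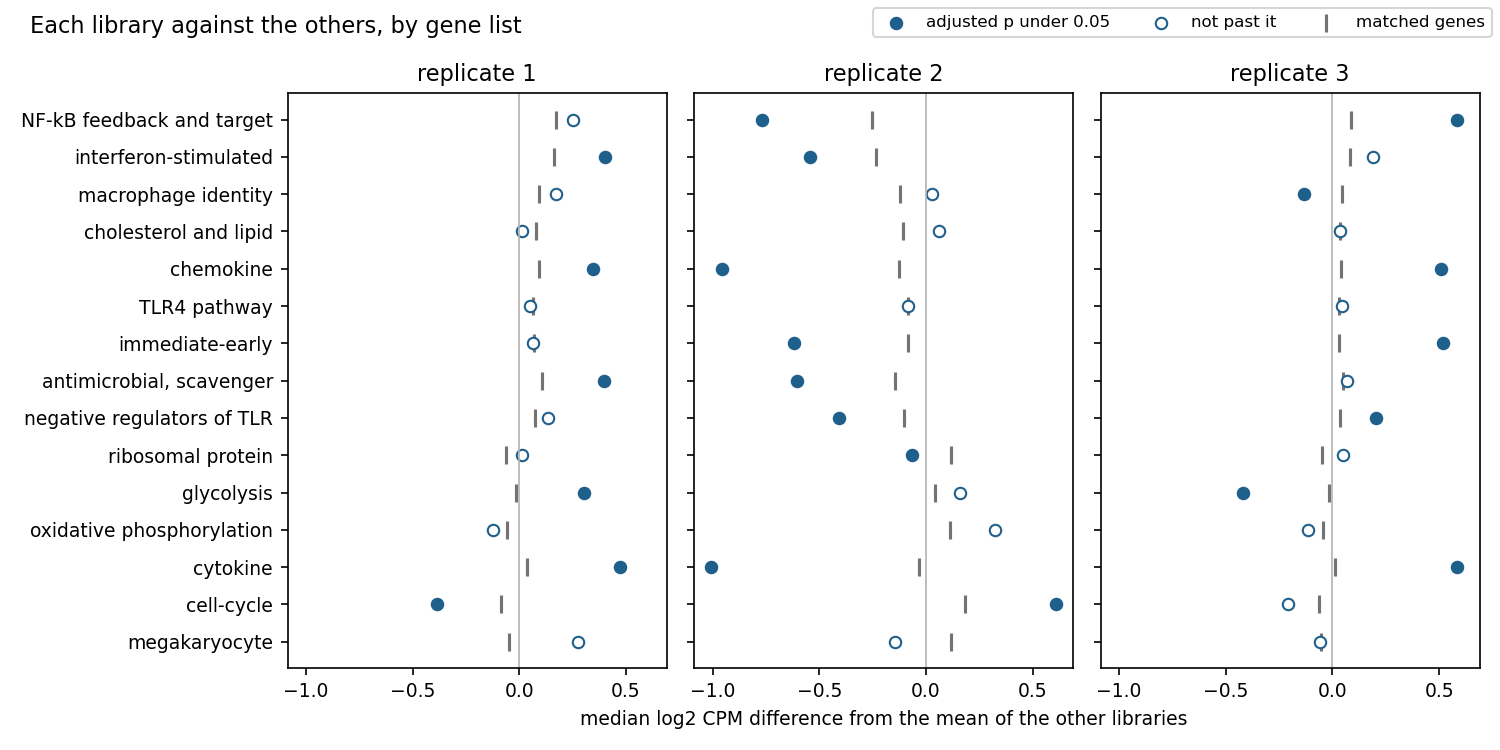
Median log2 CPM difference of each list in a library from the mean of the other libraries, 1 panel per replicate, with filled points for an adjusted permutation p under 0.05 and grey bars for genes matched on expression. Cytokine genes (-1.01) and chemokine genes (-0.96) lie farthest to the left in replicate 2, where cell-cycle genes (0.61) lie to the right, and the ribosomal protein point (-0.06) lies left of its matched genes (0.12), with both above 0 under total count scaling.

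The share of a gene's TPM in transcripts annotated with a retained intron describes how its signal was divided between annotated transcripts. Both quantifications used annotated transcripts only, so other intron reads are not counted and the share is no measure of unspliced RNA. TPM also divides by length, so short annotated transcripts weigh more. Over 6285 genes, the median of this share was 42.1% ± 2.22 (SD, n = 3), with 41.0%, 44.6% and 40.6% per library, and 2296 genes had a share above 50%. Chemokine genes had 63.5% ± 1.46 over 7 genes, ribosomal protein genes 57.3% ± 3.64 over 62, NF-kB genes 54.2% ± 4.31 over 17, antimicrobial genes 53.6% ± 0.0888 over 7, oxidative phosphorylation genes 52.3% ± 4.43 over 16 and interferon-stimulated genes 50.7% ± 2.58 over 18. Toll-like receptor 4 pathway components had 47.4% ± 3.84, cholesterol and lipid genes 44.4% ± 4.54, immediate-early genes 42.9% ± 3.55 and glycolysis genes 39.3% ± 4.91. Macrophage identity genes had 36.0% ± 14.5, cell-cycle genes 35.0% ± 11.5 and negative regulators 35.0% ± 1.40. Cell-cycle genes had 29.9%, 48.2% and 27.0% in replicates 1, 2 and 3. The median over all genes was 43.4% in the quantification made from the reads, with chemokine genes at 60.8%, ribosomal protein genes at 57.0% and antimicrobial genes at 56.1%. NF-kB genes had 45.4% there. Interferon-stimulated genes (41.6%), oxidative phosphorylation genes (41.3%) and immediate-early genes (42.6%) lay below that median and glycolysis genes (45.4%) above it, so the place of these 4 lists relative to all genes turned. A share of 100% was found for 22 genes, of which Fbxw9, Traf4, Sdr39u1, Ctsw and Rps26 stood at the top of the tied order, with mean levels between 1.49 and 5.72 TPM. Short reads do not show a whole transcript, and Spearman's rho of this share between the quantifications was 0.739 across 6259 genes.

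Gene levels were compared between the quantification from the alignment and that from the reads to show how far they depend on the method. Spearman's rho across 10952 protein-coding genes was 0.934 ± 0.00726 (SD, n = 3). NF-kB and interferon-stimulated genes stood above cytokine genes in both quantifications. Of 116 named genes, 71 moved by more than 1 SD of the replicates, among them Alas2, Irak2 and the small nucleolar RNA genes, and 45 did not, among them Nos2.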

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

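The tests of scaling, of cytoplasmic RNA and of Y-linked genes were chosen only after the results were seen. The phiX control, sequence added to sequencing runs and not part of the sample, had 157826 counts in replicate 1, 55880 in replicate 2 and 46173 in replicate 3, above the limit of 3 counts that a count of 0 allows. It lies outside the measured genes and entered no comparison.

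Members of the 7 response lists lower in replicate 2 (128 genes, 113 of them lower) had a median log2 CPM difference of -0.69 from the other libraries, against -0.16 for genes matched on expression. Scaling did not account for the whole difference, since the median nearest to 0 over TMM, DESeq2 and total count scaling was -0.53. GC content and transcript length also left a deviation of -0.48 from genes matched on all 3 properties, below each of 10000 random lists. A larger share of cytoplasmic RNA in replicate 2 could not be excluded, because the ribosomal protein share was 1.12 times that of the other libraries, above the limit of 1.1 set for exclusion, while the mitochondrial share was 0.694 times. Replicate 2 also had the highest shares of Gm26917 and Gm42418 (21.4%) and of nuclear rRNA genes (0.803%). Its median retained-intron share was the highest too (44.6%). Whether these go with the lower response genes was not tested. A difference in RNA input, culture or timing also stays open, each library having its own input, and no biological explanation was tested, as there is 1 group.

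Gm26917 (ENSMUSG00000097971.3, 39843013 to 39846341) and Gm42418 (ENSMUSG00000098178.1, 39846958 to 39848788) on chromosome 17 held 17.5% of counts, and Gm42418 lies wholly inside the rRNA gene CT010467.1 (39846353 to 39848827, opposite strand), with Gm26917 next to it. Of the words of 25 bases in Gm42418, 97.0% occur in CT010467.1, but the overlap of their coordinates fixes this value, so for Gm42418 reads from ribosomal RNA and a long non-coding RNA cannot be told apart. For Gm26917, 0% of its words occur in annotated rRNA genes, although a bound of under 5% had been set against this explanation on the assumption that the annotation holds the large-subunit rRNA. The longest annotated nuclear rRNA transcript has 1849 bases, too short to hold it. Any ribosomal RNA sequence outside annotated rRNA genes would not be matched either. The comparison therefore cannot tell ribosomal RNA from a long non-coding RNA for Gm26917, which lies on the same strand as Gm42418. The CPM in replicates 2 and 3 was 1.39 and 1.08 times that in replicate 1 for Gm26917, 2.25 and 1.56 times for Gm42418, 3.20 and 2.08 times for CT010467.1 and 1.04 and 1.27 times for Malat1, and no biological explanation was tested.

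The quantification made from the reads counted 1.52, 1.80 and 1.71 times as many fragments in annotated genes as the one from the alignment, and 23626 genes had a mean of at least 10 counts against 14320 (before rounding). Of 9371 genes that passed in the former only, 4824 had 0 counts in each library of the latter and 3799 were protein-coding. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 674, 1236 and 1055 counts together in the former, against 0, 1 and 1 in the latter. The latter held at most 0.0948% of these counts in any library but at least 57.1% of those of the X-linked partners, which argues against true Y-linked transcripts and is consistent with fragments from other sequences being assigned to these 4 genes, with other genes untested. Gm26917, Gm42418 and CT010467.1 together held at most 28.1% of the difference in any library, which argues against them as its main part.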

How the results depend on the processing

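TPM rescaled over protein-coding genes for list differences, total count scaling for library differences and the alternatives for single genes were chosen only after the results were seen. No paired analysis was possible because there is 1 group. Of the alternatives to the main results 334 kept direction and side of the threshold or moved within the replicate spread, among them all 64 for list differences, although 13 of these moved the fold over 1.5 times, while 17 moved, 9 lost and 8 gained a call and 2 reversed. Leaving out 1 of 3 values cannot move a mean by 1 SD, so it says nothing about the stability of class shares, the retained-intron share or TPM. DESeq2 and total count scaling cannot change the calls of library differences, so they say nothing about the stability of these calls.

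The lowest agreement of replicates was 0.962 with a mean of at least 1 TPM and 0.978 with CPM. As TPM shares the classes held 30.1% (protein-coding), 12.9% (long non-coding), 7.19% (Gm26917 and Gm42418), 2.99% (Malat1) and 2.76% (other long non-coding). The others held 53.6% (small structural), 1.34% (nuclear rRNA), 0.0578% (mitochondrial), 0.0103% (histone) and 0.163% (ribosomal protein). TPM divides by length, which weights short transcripts, but annotated length alone does not account for the small structural share. From the reads, Malat1 held 6.76%, other long non-coding genes 6.40% and nuclear rRNA genes 1.56%, and the cause was not tested.

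With the background limited to a mean of at least 10 counts, which removes undetected genes by construction, percentiles were 18.9 for cell-cycle (reversed), 66.4 for glycolysis, 60.4 for oxidative phosphorylation, 5.14 for dendritic cell and 0.881 for fibroblast lists. With CPM oxidative phosphorylation lay at 71.2, and from the reads natural killer cell markers at 16.2 and mast cell markers at 9.23, and the cause was not tested. The retained-intron share was 44.8% with at least 10 TPM.

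Without a replicate, 3912 to 6325 genes varied beyond counting noise. The median SD of log2 CPM ranged from 0.20 (reversed, without replicate 2) to 0.63 for cell-cycle, 0.13 to 0.40 for glycolysis, 0.10 to 0.44 for interferon-stimulated, 0.16 to 0.20 for macrophage identity, 0.14 to 0.18 for ribosomal protein, 0.26 to 0.52 for immediate-early genes and 0.20 to 0.42 for negative regulators. From the reads it was 0.36 for cell-cycle and 0.38 for glycolysis genes, and the cause was not tested. Of the 22 library differences, 22 were shared under DESeq2 and total count scaling. A scaling moves list and matched genes alike, so this outcome was fixed in advance and tests nothing. With at least 100 counts 18 were shared, both cell-cycle differences had too few genes to be tested, and antimicrobial genes in replicate 1 (0.20) and ribosomal protein genes in replicate 2 (0.02) lost their call. From the reads 21 were shared, without cell-cycle genes in replicate 1 (-0.16). Gained from the reads were macrophage identity (0.13) and cholesterol and lipid genes (0.13) in replicate 2 and T cell markers (0.34, 8 genes, too few in the gene tables to be tested) in replicate 3, and the cause was not tested. In simulated data the spread test found no list changed 1.5-fold in a library, so such changes can be missed.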

Other observations

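The gene groups in this part, the comparison of the other heat shock genes in replicates 2 and 3 and the test of the sex of the mice were chosen only after the values were seen. Genes of antigen presentation by MHC class I were abundant, with a median of 111 TPM over 10 genes (percentile 97.6), and included H2-D1 with 903 ± 171 and Nlrc5, their transcriptional activator, with 360 ± 15.8 (SD, n = 3). MHC class II genes were lower, with a median of 13.3 TPM over 7 genes, among them Cd74 with 64.0 ± 14.8. Guanylate-binding protein genes, which act against intracellular microbes, had a median of 121 TPM over 8 genes (percentile 97.9), led by Gbp5 with 550 ± 213. In replicate 2 the MHC class II genes had a median log2 CPM difference of -0.76 from the other libraries, against 0.07 for genes matched on expression, and the guanylate-binding protein genes -0.73 against -0.26, with 0 of 7 and 0 of 8 members higher. The MHC class I genes had -0.25 against -0.16, above 21.3% of matched lists. Splicing factor genes had a median of 217 TPM over 16 genes (percentile 99.0).

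Among long non-coding RNAs, Mir155hg, the host gene of an inflammatory microRNA, had 210 ± 95.5 TPM, Dleu2 150 ± 22.4, Mir22hg 134 ± 26.1, Gas5 126 ± 22.8 and Firre 88.0 ± 15.7. Circadian clock genes had a median log2 CPM difference of -0.81 in replicate 3, with 1 of 10 members higher, and the 7 other than Per1, Per2 and Cry2 had -0.37, also with 1 higher.

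The heat shock genes Hspa1a and Hspa1b, a pair of near-identical genes, had 9.70 and 7.68 TPM in replicate 1, against 1.40 and 0.820 in replicate 2 and 3.11 and 2.81 in replicate 3. A candidate explanation is a heat shock response in replicate 1. The median log2 CPM difference of 12 other heat shock genes was 0.27 there, with 10 higher, against 0.02 for matched genes, but it was -0.40 in replicate 2 and 0.23 in replicate 3, and between replicates 1 and 3 it was 0.04. This lies between the 0.5 set in advance for such a response and the 0.2 set against it, so the test leaves it open, and Dnajb1 had 0.590, 1.53 and 1.34 TPM in replicates 1, 2 and 3.

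The labels give no sex. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had at most 1 count in any library of the quantification from the alignment, while their X-linked partners had 6412, 7631 and 7514 counts and Xist had 1147 ± 136 TPM. The quantification from the reads gave these Y-linked genes 674, 1236 and 1055 counts, but the alignment held at most 0.0948% of these against at least 57.1% of the counts of the X-linked partners. These values are consistent with cells from female mice and argue against male mice as the source.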
